A study of Homo sapiens with 32 samples.

How the data were processed

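Total RNA was sequenced from human adipose-derived stem cells of abdominal (ABD) and gluteofemoral (GF) subcutaneous fat, in which the long noncoding RNA HOTAIR was either overexpressed from a lentivirus (ABD) or silenced with siRNA (GF), per the labels' protocols. The 32 libraries form 4 groups: ABD control, ABD overexpression, GF control and GF silencing. Each group holds 4 numbered cell sources with 2 technical replicate runs per source. What the control cells received is not stated, and the labels do not say whether a number marks the same donor in both depots. The read aligner STAR 2.7.7a, SAMtools 1.3.1, bedtools 2.29.2, featureCounts, edgeR and the genome build hg19 are named in the submitters' processing notes. The gene annotation, strand setting and library kit were not given in the sources used here.

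The authors deposited 2 tables of raw counts per gene, 1 for each depot, with 59304 gene rows in each. These whole-number counts were used as deposited. Deposited tables of TPM, 4 in all, were not used for levels: their 32 value columns carry the same names in each table and could not be matched to samples. Gene positions come from these tables, counted from 0 at both ends per the values, with 1 added here. Rows for XIST, TSIX and Y-linked genes, 496 in all, were left out of the tests.

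The 2 runs of a source differed by about as much as counting noise. Chi-square per degree of freedom lay between 1.006 and 1.037 in ABD libraries and between 1.042 and 1.135 in GF libraries. They were therefore summed and counted as 1 sample, so n = 4 per group. Nothing states that the numbered sources are separate donors, so p-values measure only the spread between these samples. Summed totals ranged from 7932488 to 42767103 counts. A floor of 3 counts was used for libraries at 0. Floors and intervals cover counting error only.

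Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with the edgeR quasi-likelihood test with robust dispersion. Benjamini-Hochberg adjusted p-values were held against 0.05. The overexpression and silencing comparisons had the source number as a block, and the comparison of GF with ABD controls had none. Levels are counts divided by the scaled library size (CPM), as mean ± SD. Fitted log2 fold changes carry a standard error (SE), computed as their size divided by the square root of the test's F statistic. It reflects the fitted model and can be far smaller than the spread of the 4 sources. The programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with matplotlib 3.10.9 for the plots. The HOTAIR level was also compared with two-sided exact permutation tests, chosen after the data were examined.

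The pairing was checked by the correlation, across genes, of each library's deviation from its group mean. Same-numbered GF control and silenced libraries had r of 0.863, 0.838, 0.912 and 0.93, each the highest for that control. In ABD cells r was 0.919 and 0.899 for 2 sources and 0.111 and 0.152 for the others. All were over 0.1, so the labelled pairing was kept. Those 2 sources matched each other's overexpression library better, with r of 0.753 and 0.898. Passing the limit of 0.1 therefore does not show that these 2 labelled pairs are right.

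The 32 gene lists were fixed before the data were examined, as were the samples, the tests and all alternatives not named as added. They were tested with camera at a preset correlation of 0.01 where at least 4 members were measured. Camera with an estimated correlation and fry served as alternatives. Named genes followed a fixed rule: HOTAIR, then the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 1 CPM. They had to move the same way in all 4 sources, or not overlap between control groups. Clone names, pseudogenes, XIST and Y-linked genes were left out. Where fewer than 5 passed, the 5 smallest p in each direction were taken as not passing. Up to 4 members past the threshold were named from each list, and then up to 10 genes passing in both manipulations. HOX genes could be named whatever their p, with values only. Some genes that met the rule are not reported here.

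Other settings were DESeq2's Wald test, size factors of the RLE type, no filter on low counts, either technical run alone, the other choice on the block, and each source left out. Settings added after the data were examined were an exchange of 2 overexpression libraries, the 2 other sources alone, and controls without ABD control source 4.

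The edgeR test was tried on simulated counts with 50 genes changed at each fold size. For silencing, with 16865 genes, it recovered 40 of 50 genes at 1.5-fold and 48 of 50 at 2-fold, with 18 unchanged genes called. For overexpression as labelled, with 16610 genes, it recovered 5 of 50 at 1.5-fold, 28 of 50 at 2-fold and 46 of 50 at 4-fold, with 17 unchanged genes called. With 2 overexpression libraries exchanged it recovered 42 of 50 at 1.5-fold and 49 of 50 at 2-fold, with 25 unchanged genes called. For the controls, with 15352 genes, it recovered 1 of 50 at 1.5-fold, 14 of 50 at 2-fold and 35 of 50 at 4-fold, with 6 unchanged genes called. Simulated counts were drawn independently for each gene around fitted means. They lack shifts shared by many genes, as between mismatched libraries, so recovery in the real overexpression comparison can be lower. HOTAIR itself did not pass there at a log2 fold change of 4.08.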

Results

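RNA from 16 cultures of adipose-derived stem cells, the precursor cells of fat tissue, was profiled to find genes that respond to HOTAIR. HOTAIR is a long noncoding RNA transcribed from the HOXC cluster, antisense to the HOXC genes. Cells from abdominal fat (ABD) overexpressed it and cells from gluteofemoral fat (GF) were depleted of it, each beside control cells, with 4 numbered sources per group. Control ABD cells had 36787149, 24949557, 35022295 and 7932488 counts in sources 1 to 4, and ABD cells with HOTAIR overexpression had 23830418, 36262305, 20172111 and 33015265. Totals were 27410909, 38142298, 26927062 and 41121420 in control GF cells and 27788211, 33858505, 35851528 and 42767103 in silenced GF cells. ABD control source 4 stood apart in makeup as well as depth. The collagen genes COL1A1, COL1A2 and COL3A1 took 3.48% of its counts (95% Wilson interval 3.46% to 3.49%), against 11.7% to 12.2% in the other ABD controls, and mitochondrial transcripts took 2.40% (2.39% to 2.41%), against 0.123% to 0.255%. Overexpression libraries had 7.48% to 12.9% and 0.131% to 0.858%.

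The targeted gene was examined first. HOTAIR lies on chromosome 12 from 54356092 to 54368740 (hg19), and its span overlaps that of HOXC11 (54366910 to 54371427). Reads of the overlapping part cannot be told apart without strand. In ABD control cells the normalised level of HOTAIR was 0.12, 0.88, 0.18 and 0 CPM in sources 1 to 4, from 4, 21, 6 and 0 counts. The count of 0 allows up to 0.274 CPM. With overexpression it was at 4.78, 4.94, 3.76 and 4.27 CPM, higher in 4 of 4 sources, with HOXC11 at 0.54 CPM against 0.48 CPM in controls when scaled over the ABD libraries alone. Every overexpressing culture lay above every ABD control (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). This test ignored the source number, and within sources 4 pairs allow no exact permutation p below 0.125. The fitted log2 fold change was 4.08 ± 0.63 (SE, n = 4). Its unadjusted p of 9.36e-04 did not pass the correction over all genes in edgeR (adjusted p = 1). DESeq2 gave an adjusted p of 1.15e-06, and across the settings tried the adjusted p reached from that value to 1.

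GF controls expressed HOTAIR at 1.27, 4.82, 2.93 and 6.06 CPM, a range that spans the levels of the overexpressing ABD cells. Silencing left 56.1%, 24.9%, 16% and 29.1% of it in sources 1 to 4. HOTAIR thus averaged 1.04 ± 0.57 CPM in silenced GF cells (SD, n = 4) and 3.77 ± 2.11 CPM in their controls. The log2 fold change was -1.88 ± 0.20 (SE, edgeR adjusted p = 6.73e-04), with a fall in 4 of 4 sources. Within sources, 4 pairs allow no exact permutation p below 0.125, and that value was obtained. The difference between GF and ABD controls was 3.55 ± 0.85 on the log2 scale (edgeR adjusted p = 0.0504, between 2.52e-04 and 0.202 over the other settings), not past the threshold, although no GF control lay below an ABD control (two-sided exact permutation p = 0.0286).

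**Figure D1:**
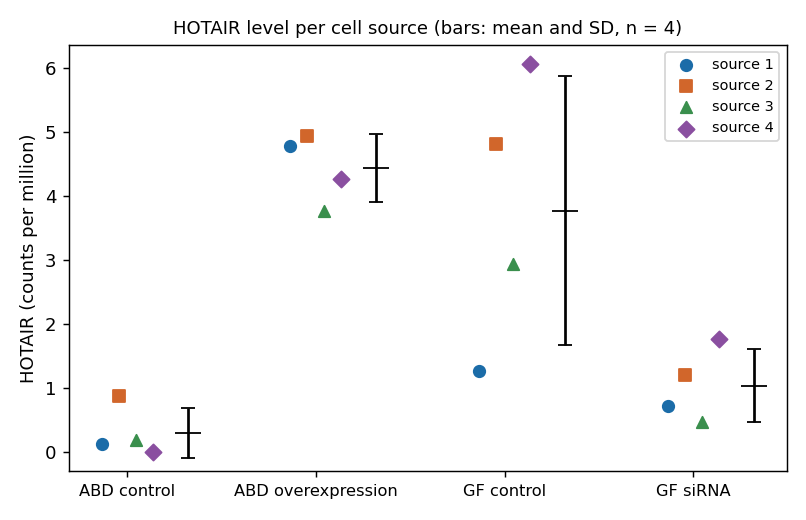
HOTAIR level in CPM (vertical axis) in the 4 groups, with 1 point per cell source and a bar for the mean and SD of n = 4. Overexpressing ABD cells sit between 3.76 and 4.94 CPM, all above the ABD controls, and silenced GF cells sit below their own controls in each source.

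The silencing comparison asks which genes respond to the loss of HOTAIR in GF cells. Chemokines and other inflammatory genes rose most. CXCL8, which attracts neutrophils, rose from 38.8 ± 40.2 to 144 ± 150 CPM (SD, n = 4), a log2 fold change of 1.83 ± 0.12 (SE). CXCL1 rose by 1.56 ± 0.18, from 30.4 to 87.3 CPM. Of the monocyte and T cell attractants, CCL8 rose by 2.48 ± 0.20, CCL5 by 2.25 ± 0.26, CCL7 by 1.64 ± 0.19 and CCL20 by 1.95 ± 0.20 on the log2 scale. Each did so in 4 of 4 sources, which the rule for naming the largest rises required. The rises also took in CXCL11 (4.41 ± 0.55) and GBP5 (2.39 ± 0.30), both interferon-inducible. CXCL11 changed by 5.40, 0.67, 4.44 and 0.88 in sources 1 to 4, a wider spread than its SE. GRIP2 rose by 1.92 ± 0.33 and the Notch ligand DNER by 1.79 ± 0.23. All of these were below 10 CPM in silenced cells except CXCL8 and CXCL1.

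Of the 27 measured inflammatory cytokines and NF-kB targets, 16 rose and none fell, and 25 rose when adjusted over the list alone. Their median log2 fold change was 0.86, and all 27 had a positive sign. ICAM1, an adhesion molecule for leukocytes, rose by 0.63 ± 0.04, the cytokine gene IL1B by 0.97 ± 0.08, CXCL3 by 1.23 ± 0.10 and the apoptosis inhibitor BIRC3 by 0.86 ± 0.08. Camera called the list (adjusted p = 6.16e-67), but not with an estimated correlation (adjusted p = 0.301). Fry gave an adjusted p of 0.0444. The median change of the list was 1.06, 0.82, 0.89 and 0.41 in sources 1 to 4. Beside these genes, LIF rose by 1.01 ± 0.09 and IL11 by 0.95 ± 0.11. These related cytokines were counted among 5 of 23 genes of the TGF-beta and YAP response that rose (8 rose and 7 fell adjusted over the list alone). That list itself was not called (adjusted p = 0.0682), and 2 of its genes rose without source 2 and 3 without source 3.

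Interferon response genes divided by source. Of 35 measured members 2 rose, CXCL11 and CXCL10, and 4 when adjusted over the list alone. CXCL10 rose by 3.97 ± 0.23, from 1.84 to 30.8 CPM with an SD of 40.8 CPM after silencing. Its change was positive in 3 of 4 sources. It was 3.91, 2.12, 4.17 and 0 in sources 1 to 4, a far wider spread than the SE. The list's median change was 2.39 and 2.25 in sources 1 and 3, with all 35 members positive, and 0.08 and -0.08 in sources 2 and 4. The number that rose was 0, 4, 1 and 2 without sources 1, 2, 3 and 4. Cell cycle genes showed the reverse division: medians of 1.17 and 1.25 in sources 2 and 4, with all 37 members positive, and 0.04 and 0.02 in sources 1 and 3. CDC6, a DNA replication licensing factor, was the 1 member of 37 that rose (0.52 ± 0.11), as it was adjusted over the list alone. Without source 2, and without source 4, none passed, and without source 3 there were 9. With no filter on low counts 15 cell cycle genes rose, with DESeq2 6, and with technical run 1 or 2 alone 2 or 4. Interferon genes that rose were 4 with no filter and 4 with DESeq2. Both lists were called by camera (adjusted p = 3.45e-10 and 1.17e-10) but not with an estimated correlation (adjusted p = 0.464 for each).

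Extracellular matrix genes fell. Of 36 measured members, 12 fell and none rose (20 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.15. COL12A1, a fibril-associated collagen, went from 5630 ± 3539 to 4242 ± 2316 CPM (-0.37 ± 0.06). FBLN5, which takes part in elastic fibre assembly, changed by -0.40 ± 0.05, COL14A1 by -0.43 ± 0.07 and MFAP4 by -0.32 ± 0.06. The list was called by camera (adjusted p = 1.22e-10; adjusted p = 0.301 with an estimated correlation). The number that fell was 4, 3 and 5 without sources 1, 2 and 4. Matrix remodelling enzymes went the other way, with 5 of 22 higher (6 higher and 1 lower adjusted over the list alone). Among them were the aggrecanase ADAMTS4 (0.80 ± 0.06), the stromelysin MMP3 (0.89 ± 0.08), the urokinase receptor PLAUR (0.50 ± 0.05) and MMP14 (0.22 ± 0.05). This list had a camera adjusted p of 2.18e-05, and an adjusted p of 0.301 with an estimated correlation, and 3 rose without source 2, as without source 4.

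Smaller shifts touched other groups. Stromal cell markers included 3 of 22 that rose (3 adjusted over the list alone): ICAM1, NT5E, which encodes CD73 (0.46 ± 0.04), and ALCAM (0.26 ± 0.05). Among 16 metallothionein and oxidative stress genes, 5 rose and TXNRD1 fell by 0.28 on the log2 scale (9 rose and 2 fell adjusted over the list alone). MT2A rose by 0.76 ± 0.10 and MT1E by 0.43 ± 0.07, and reads of these near-identical copies are uncertain. Of 26 p53 target and senescence genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone), ZMAT3 by -0.30 ± 0.06 and CDKN1C by -0.52 ± 0.11. In the contractile list 2 of 18 fell (4 adjusted over the list alone), LMOD1 by -0.69 ± 0.12 and ABCC9 by -0.24 ± 0.05. Without sources 1, 2, 3 and 4 the p53 list had 4, 1, 1 and 2 lower and 0, 1, 2 and 0 higher, the metallothionein list 1, 2, 4 and 1 higher and 1, 0, 1 and 0 lower, and the contractile list 2, 1, 0 and 1 lower. With an estimated correlation these calls were lost, with an adjusted p of 0.301 for the stromal and the metallothionein lists, 0.464 for the p53 list and 0.34 for the contractile list. None of the 7 measured HOXC genes beside HOTAIR passed, and all 7 had a negative sign (median -0.15; HOXC8 was lower adjusted over the list alone). That list's camera adjusted p was 0.0331, its adjusted p with an estimated correlation was 0.385, and its fry adjusted p was 0.0142. HOXC8 had a value of -0.19 ± 0.05 and HOXC10 one of -0.15 ± 0.07. Mitochondrially encoded mRNAs, a sign of RNA quality, had 1 of 13 higher, MT-CO3 (0.20 ± 0.05), and 3 adjusted over the list alone, with medians of -0.26, 0.21, 0.07 and 0.66 in sources 1 to 4. Of 12 histone genes, whose copies share reads, H2BC5 rose (0.29 ± 0.07), and 4 rose adjusted over the list alone. Without sources 1 to 4 the mitochondrial list had 1, 0, 0 and 0 higher and the histone list 0, 0, 2 and 0. Their camera adjusted p was 0.021 and 0.00327, with an adjusted p of 0.464 for each under an estimated correlation.

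The largest falls were in genes of low to moderate level. INMT, a methyltransferase of small amines, fell from 6.52 ± 3.69 to 2.57 ± 1.32 CPM (-1.30 ± 0.18), and the iron exporter gene SLC40A1 from 9.40 to 5.22 CPM (-0.83 ± 0.10). The integrin gene ITGA8 fell from 13.6 to 6.85 CPM. IL20RA changed by -1.05 ± 0.23, RAB11FIP4 by -1.08 ± 0.19 and the kinase gene MAP2K6 by -0.91 ± 0.17. MGARP, SLC29A4, the serotonin receptor gene HTR2B and PLCE1-AS1 had log2 fold changes between -0.93 and -0.79. Each of these 10 fell in 4 of 4 sources, which the rule for naming genes required.

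Of 16865 genes tested, 420 rose and 393 fell, in total 813, and 3140 had an unadjusted p under 0.05 where 843 would be expected by chance. More than 2-fold changes numbered 54 rises and 10 falls. Without the source block edgeR called 0 genes, with 199 at an unadjusted p under 0.05, and DESeq2 with the block called 739. The total was 441, 294, 540 and 523 without sources 1, 2, 3 and 4, and 48, 38, 53 and 47 of the 78 other named genes kept their call. Camera called 13 of the 32 gene lists, of which 0 held with an estimated correlation. Fry called 8 lists, 5 of them among the 13: the inflammatory, matrix, matrix remodelling, stromal and HOXC lists.

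**Figure D2:**
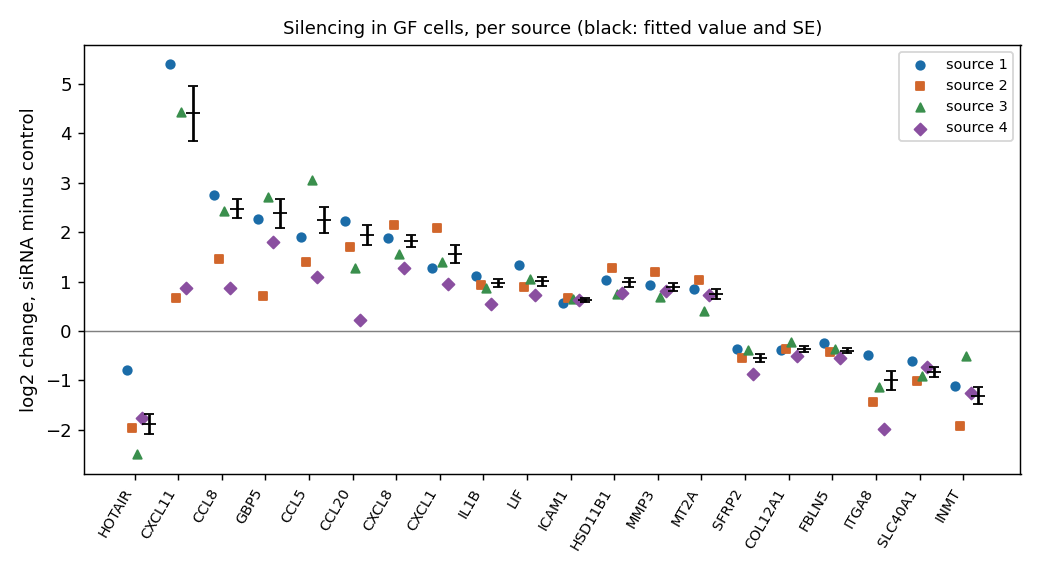
Log2 change of 20 genes after silencing in GF cells (vertical axis, siRNA minus control), with 1 coloured point per cell source and, in black, the fitted value and its SE. CXCL8 lies above 0 in each source around a fitted value of 1.83, and HOTAIR below 0 around -1.88.

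**Figure D3:**
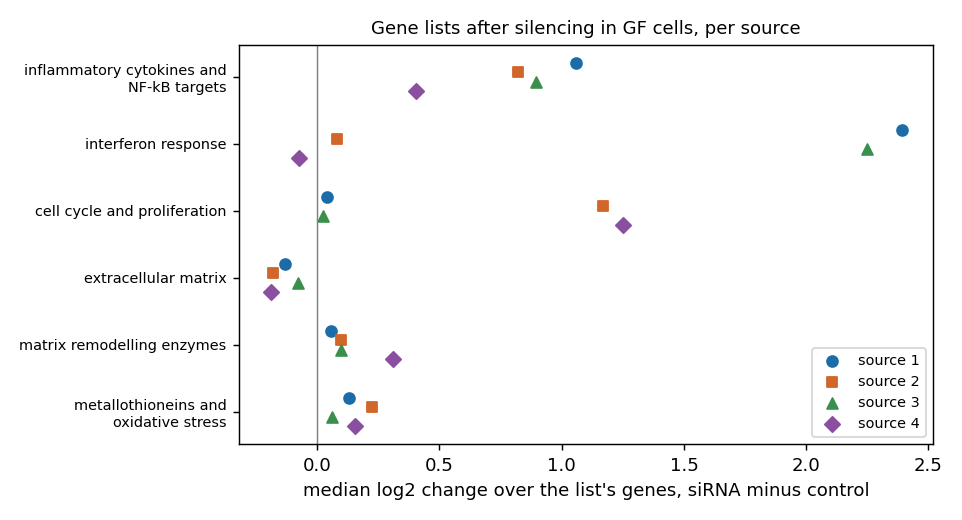
Median log2 change over the genes of 6 fixed lists (horizontal axis) after silencing, with 1 point per cell source. Interferon response genes sit at 2.39 and 2.25 in sources 1 and 3 and near 0 in the others, while cell cycle genes sit at 1.17 and 1.25 in sources 2 and 4.

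The overexpression comparison asks for the converse response in ABD cells. Apart from HOTAIR itself, the genes with the smallest p included COMP, a cartilage matrix protein, at 700 ± 478 CPM with overexpression and 380 ± 284 CPM in controls (0.98 ± 0.15). The Wnt modulator SFRP2 had a log2 fold change of 1.83 ± 0.41, SMOC2 one of 1.29 ± 0.19 and GALNT13 one of 0.71 ± 0.16. Negative values were found for COL7A1 (-0.31 ± 0.07), TRHDE-AS1 (-1.24 ± 0.31), MAPK13 (-0.29 ± 0.08), EVA1A (-0.29 ± 0.08) and ITGA3 (-0.43 ± 0.12). Each had the same sign in 4 of 4 sources, which the rule for naming genes required, and none passed the correction in edgeR. DESeq2 called 4 genes, among them HOTAIR, COMP and SFRP2.

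As labelled, gene lists gave no called member either. All 37 cell cycle genes had a negative sign (median -0.35), as did 33 of 35 interferon response genes (median -0.36), while 32 of 36 matrix genes were positive (median 0.20) and 18 of 23 BMP and GDF signalling genes (median 0.18). Camera called 12 lists, these among them, but 0 held with an estimated correlation (adjusted p = 0.597 for the matrix and BMP lists, 0.683 for cell cycle and 0.808 for interferon), and fry called 0. The medians hid opposite values. Interferon genes stood at -0.20, -0.36, -3.46 and 2.61 in sources 1 to 4, and cell cycle genes at -0.13, 0.04, 0.14 and -1.52. In the same order matrix genes stood at 0.11, 0.01, -0.27 and 0.86, and BMP and GDF genes at 0.003, 0.10, -0.16 and 0.71. These sources include those with r of 0.111 and 0.152 between same-numbered libraries. There such values can hold differences between sources and not only a response to HOTAIR. Osteogenic and chondrogenic genes were positive in 10 of 12 (median 0.18), and COMP was higher adjusted over the list alone. Camera gave this list an adjusted p of 0.00789, and one of 0.597 with an estimated correlation. Its medians also differed in sign, at 0.0529, 0.154, 0.855 and -0.322 in sources 1 to 4. In no other list of this comparison did a member pass when adjusted over the list alone. All 7 measured HOXC genes were positive, between 0.04 and 0.35, with no call.

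Of 16610 genes tested with edgeR, 0 passed, and 146 had an unadjusted p under 0.05 where 830 would be expected by chance. Expression varied more between same-numbered ABD libraries (biological coefficient of variation 0.239) than between GF ones (0.0758). When 2 overexpression libraries whose deviations matched each other's controls were exchanged, the variation was 0.0949 and 1 gene passed, STMN2. Cell cycle genes were then negative in 37 of 37 cases, interferon genes in 32 of 35 and inflammatory genes in 14 of 28. The 2 remaining sources alone, a fit added after the data were seen, gave 95, with 5 interferon and 3 matrix genes among them. With 2 samples per group, these calls rest largely on spread shared across genes. Interferon genes were negative there in 33 of 35 cases and inflammatory genes in 26 of 28 (camera adjusted p = 1.43e-27 and 2.79e-05). The inflammatory list had per-source medians of -0.39 and -0.01, with 4 and 13 of its 28 genes positive, so most of its shift came from 1 of these sources. Cell cycle genes were mixed, 14 positive and 12 negative. With an estimated correlation each list of these 2 sources had an adjusted p of 0.948 or above.

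The comparison of control cells asks how GF cells differ from ABD cells. Depot went together with the count table and the kind of experiment, so these cannot be separated. Regional patterning genes set the groups apart. TBX5, a forelimb and upper body transcription factor, was at 0.47 ± 0.14 CPM in GF and 12.1 ± 3.22 CPM in ABD controls (SD, n = 4), a log2 fold change of -4.69 ± 0.30 (SE). ZIC1 (4.19 ± 0.30), SHOX2 (2.52 ± 0.20) and TBX15 (1.40 ± 0.16) were higher in GF controls. Of 23 measured genes of this list, 6 were higher and 2 lower (8 and 2 adjusted over the list alone). The HOX genes past the threshold were lower in GF cells except HOXC11: 5 of 9 HOXA genes (7 lower and 1 higher adjusted over the list alone), 2 of 8 HOXB genes (4 lower) and 2 of 4 HOXD genes (3 lower). Examples were HOXA5 (-3.50 ± 0.31), HOXA3 (-3.46 ± 0.43), HOXD9 (-3.53 ± 0.28) and HOXB7 (-1.13 ± 0.22). HOXC11, which overlaps HOTAIR, was the 1 HOXC gene of 6 that passed, at 5.37 ± 1.22 CPM in GF and 0.49 ± 0.57 CPM in ABD controls when scaled over the controls of both depots (3.45 ± 0.68), as it was adjusted over the list alone. With an estimated correlation the adjusted p was 0.117 for the patterning, HOXA and HOXD lists and 0.383 for HOXB. Fry gave an adjusted p of 0.00216 for the patterning, HOXA and HOXD lists and 0.0259 for HOXB. Without sources 1, 2, 3 and 4 the patterning list had 1, 2, 2 and 7 higher and 1, 1, 1 and 4 lower. The lower HOXA genes then numbered 0, 1, 1 and 6, the HOXB genes 0, 0, 0 and 4 and the HOXD genes 1, 1, 1 and 4, and of these fits HOXC11 passed in those without source 2 and without source 4.

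Sterol biosynthesis genes were higher in GF controls in 20 of 22 cases (21 adjusted over the list alone), with all 22 positive and a median log2 fold change of 2.21. CYP51A1, the lanosterol demethylase, was at 193 ± 50.1 CPM in GF and 39.1 ± 5.90 CPM in ABD controls (2.31 ± 0.22). The squalene epoxidase SQLE (2.53 ± 0.25) and the sterol oxidase MSMO1 (2.47 ± 0.24) were also higher. The list had a camera adjusted p of 1.93e-50 and an adjusted p of 0.114 with an estimated correlation. Fry gave an adjusted p of 0.00216. The number of sterol genes called was 1, 0, 1 and 21 without sources 1, 2, 3 and 4, at medians of 1.95, 2.06, 2.27 and 2.42. Lipid storage genes had 3 of 22 higher (7 higher and 1 lower adjusted over the list alone), the desaturase SCD (2.51 ± 0.57), the fatty acid synthase FASN (294 against 128 CPM) and LPIN1 (1.41 ± 0.26), with an adjusted p of 0.154 under an estimated correlation. None of the lipid genes passed without source 1, 2 or 3, and 7 were higher without source 4 and 5 without ABD control source 4 alone.

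Further differences lay in stress and stromal genes. Metallothionein and oxidative stress genes were higher in 7 of 14 cases (10 adjusted over the list alone), such as MT1X (2.25 ± 0.34) and NQO1 (0.99 ± 0.20). Of 17 immediate early genes, 5 were higher (11 adjusted over the list alone), among them FOS, at 504 against 62.9 CPM, and JUNB (1.84 ± 0.24). The adjusted p with an estimated correlation was 0.152 and 0.168 for these lists. KLF4, an early adipogenic regulator, was at 176 ± 93.9 CPM in GF and 14.4 ± 2.88 CPM in ABD controls (3.61 ± 0.36), and ZNF423, a preadipocyte factor, differed by 1.22 ± 0.26. They were the 2 called among 19 such regulators (3 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). The progenitor markers PI16 (3.28 ± 0.58) and PDGFRA (1.53 ± 0.34) were higher in GF controls and the pericyte marker MCAM was lower (-3.69 ± 0.60), but the pericyte marker CSPG4 (1.64 ± 0.31) and the smooth muscle actin gene ACTG2 (5.05 ± 0.99) were higher. The contractile and pericyte list had 2 of 18 higher and 1 lower (2 and 5 adjusted over the list alone) and was not called by camera, nor with an estimated correlation (adjusted p = 0.751). No gene of it passed without source 1, 2 or 3, and 10 were lower without source 4, 8 without ABD control source 4 alone and 5 with DESeq2. Of 22 stromal markers 3 were higher and 1 lower, as adjusted over the list alone, and the list was not called (adjusted p = 0.101). INHBA, which encodes an activin subunit, was at 156 ± 134 CPM in GF and 1414 ± 748 CPM in ABD controls (-3.18 ± 0.67), and with PMEPA1 (-1.58 ± 0.37) made up the 2 called of 23 TGF-beta and YAP response genes (2 adjusted over the list alone; adjusted p = 0.526 with an estimated correlation). The TGF-beta and YAP genes called lower were 0, 0, 0 and 9 without sources 1 to 4, and 6 without ABD control source 4. In the same order the metallothionein list had 0, 0, 0 and 11 higher, immediate early genes 0, 0, 0 and 5, stromal markers 0, 0, 0 and 5 (5 higher and 2 lower without ABD control source 4 alone), and adipogenic regulators 1, 1, 0 and 5.

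Among the widest differences, the imprinted RNA H19 was at 957 ± 681 CPM in GF and 6.42 ± 6.73 CPM in ABD controls (7.27 ± 1.28), and the phosphatase ALPL at 172 ± 106 and 2.26 ± 1.52 CPM (6.27 ± 0.97). ADH1B, an alcohol dehydrogenase, averaged 16.7 CPM in GF controls and had 1 count over all ABD controls. CPXM1 (6.62 ± 1.11), XPNPEP2 (6.71 ± 0.75), LSP1 (7.05 ± 0.85) and COL21A1 (6.15 ± 0.67) were also higher in GF controls. In the other direction stood the smooth muscle coactivator MYOCD, at 0.21 ± 0.17 CPM in GF and 18.2 ± 23.7 CPM in ABD controls (-6.45 ± 1.44), the receptor FGFR2 (-5.27 ± 0.87), PLPP4 (-5.16 ± 0.61), TRHDE (-5.12 ± 0.84), PCDH10 (-5.46 ± 0.66), SBSPON (-5.20 ± 1.16) and TRPM2 (-4.71 ± 0.60). CALB2, a mesothelial marker, was at 0.04 ± 0.05 and 3.32 ± 1.97 CPM in the same order, and LINC01561 had 3 counts over all GF controls against 368. For some genes 1 source gave most ABD control counts: 494 of 581 for SBSPON, 931 of 1363 for TRHDE and 1645 of 2153 for MYOCD.

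Of 15352 genes tested, 454 were higher and 349 lower in GF controls, in total 803, with 3791 at an unadjusted p under 0.05 where 768 would be expected by chance. The total was 7, 16, 20 and 2540 without sources 1, 2, 3 and 4, 2051 without ABD control source 4 alone, and 2260 with DESeq2. Of the 74 other named genes, 5, 8, 8 and 73 kept their call without sources 1 to 4.

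**Figure D4:**
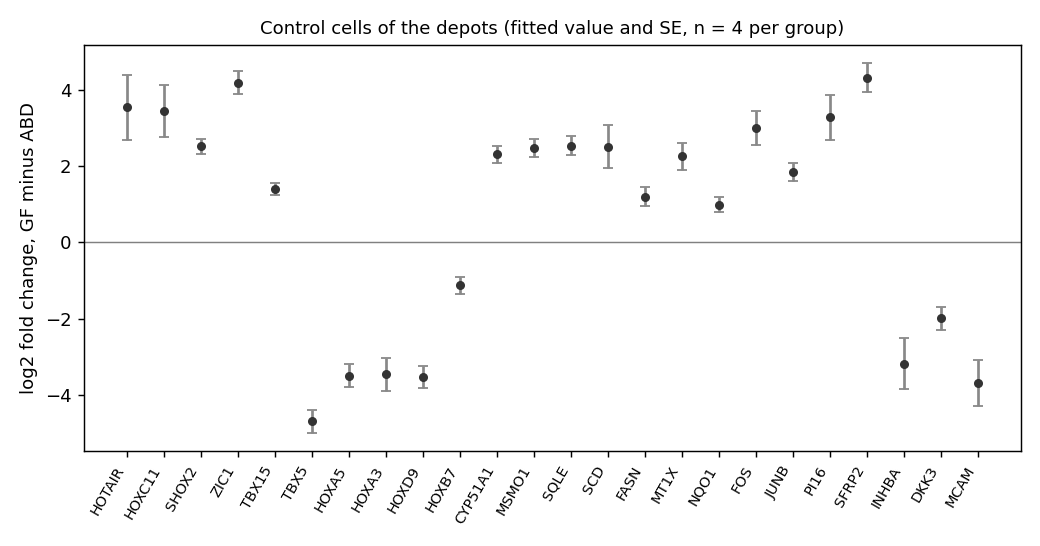
Log2 fold change of 24 genes between GF and ABD control cells (vertical axis), as the fitted value and its SE with n = 4 per group. SHOX2 and ZIC1 lie above 0 and TBX5 at -4.69, while CYP51A1, MSMO1 and SQLE lie between 2.31 and 2.53; HOTAIR did not pass the threshold.

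Finally, the manipulations were set against each other over the 15685 genes tested in both. With edgeR no gene was called in both, since none was called under overexpression, and DESeq2 called 2 in both, HOTAIR and SFRP2. Genes that rose after silencing had a negative sign under overexpression in 67.0% of 403 cases, and those that fell in 18.6% of 393, against 47.1% of all genes. Camera gave unadjusted p-values of 6.07e-06 and 5.07e-10 for these sets, but p = 0.0763 and p = 0.271 with an estimated correlation, and fry gave p = 0.165 and p = 0.458. In the 2 sources left without the libraries that matched each other's controls, chosen after the data were seen, the shares were 64.4% of 376 and 36.3% of 391, against 49.4%. Across all genes r was -0.0826 there and -0.217 as labelled, and genes are not independent replicates. SFRP2 fell by 0.54 on the log2 scale after silencing (adjusted p = 0.00985 in edgeR) and had a value of 1.83 with overexpression that did not pass.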

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

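The tests of exchanged labels, of leukocytes, of the HOTAIR level itself and of depot against treatment were chosen only after the results were seen. In 254 sets of 4 values, 20 had a highest or lowest value farther from the rest than Dixon's 95% limit. Chance flags about 1 in 20 groups, here 12.7.

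ABD control source 4 stood apart in its share of collagen counts (3.48%, 95% Wilson interval 3.46% to 3.49%, against 11.7% to 12.2%), mitochondrial counts (2.40%, 2.39% to 2.41%, against 0.123% to 0.255%) and RN7S counts (0.512%, 0.507% to 0.517%, against 0.214% to 0.257%). Between ABD controls the same source stood apart in log2 CPM of CYP19A1 (-0.41), GDF10 (0.32, the others 0.93 to 1.04) and IGF1R (6.67, the others 6.97 to 7.03). ADH1B was at -3.34 in source 3, set apart by its 1 count, and HOXB7 at 3.15 in source 2. Among GF controls, source 4 was lowest for LSP1 (3.39, the others 5.36 to 5.64), ALPL (3.86, the others 7.72 to 7.92) and COL14A1 (5.63, the others 7.30 to 7.43), and HOXB8 was at -2.74 in source 2.

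After silencing, 1 source stood apart in log2 change for AKR1C1 (0.0519 in source 4, the others 0.48 to 0.49), ALCAM (0.14 in source 1, the others 0.29 to 0.30), ABCC9 (-0.42 in source 1), MT-CO3 (0.35 in source 1), PKM (0.29 in source 2) and PLCE1-AS1 (-1.02 in source 2). With overexpression it did so for COL7A1 (-0.43 in source 3) and TRHDE-AS1 (-0.48 in source 1).

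In 2 of the 4 ABD sources, control and overexpression libraries of the same number deviated together less (r = 0.111 and 0.152) than the exchanged ones (r = 0.753 and 0.898). Unequal depth is argued against: with all ABD libraries thinned to 7932488 counts, the exchanged correlation still exceeded the other by at least 0.565. A candidate explanation is that 2 overexpression libraries carry each other's number. The difference between these sources ran against the GF controls in the overexpression libraries (r = -0.229 across 11706 genes, which are not independent replicates) and against the silenced GF libraries (r = -0.376), while in the ABD controls it had r = 0.0428 and 0.211 with these. This points to the overexpression libraries as those out of place only if a number marks the same source in both depots. That is not stated, so the explanation stays open, and no biological explanation was tested. With the libraries exchanged, the biological coefficient of variation went from 0.239 to 0.0949. The labelled pairs may thus join unlike sources, and the count of 0 genes under overexpression rests on them.

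Inflammatory genes rose after silencing in GF cells. Leukocytes among the silenced cells are argued against by marker levels: the median of 20 leukocyte markers was 0.00306 CPM, with PTPRC at 0.048 and LYZ at 0.0321 CPM, while the 16 called inflammatory genes rose by a median of 13.0 CPM. CD14 was the highest marker at 2.95 CPM, against 2.98 CPM in controls, and stromal cells also express it. CSF1R (1.26 against 0.949 CPM), CD163 (0.739 against 0.53) and FCER1G (0.514 against 0.284) were higher after silencing. CD79A (0.124 against 0.152), PTPRC (against 0.0825) and CD52 (0.0373 against 0.0718) were lower. Lymphocyte markers such as CD3E and MS4A1 were at 0 and lowered the median, so a small number of macrophages is not excluded. CD68, at 0 in each library, may be lost in the counting, and without it the median is that of MRC1 (0.00611 CPM). Unequal depth is argued against too, since 16 of the 16 genes stayed past the threshold with every GF library thinned to 26927062 counts. Whether the HOTAIR level itself is the cause remains open: under overexpression 12 of the 16 were negative (median -0.17), with a fry p of 0.565, and a response to the siRNA as such was not tested.

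Sterol genes were higher in GF than in ABD controls. The control reagents alone are argued against, because silenced GF cells exceeded overexpressing ABD cells by a median of 2.15 over the same 22 genes. The shallow ABD control is argued against as well, with a median of 2.25 without it. Depot, virus against siRNA, and batch cannot be told apart, since 0 of the HOTAIR manipulations were shared by both depots, and a depot difference is possibly the source but untested.

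For the controls, 1 of 35 splits of the 8 libraries, the real one itself, gave 803 genes, with 2 as the highest other. That is the smallest share that 35 splits allow, and it argues against chance for the number of genes only if sources are not shared between depots. If they are, splits that keep the pairs would be too few to tell. For gene lists chance is not argued against: 13 of 35 splits gave at least the 12 lists called, with 18 as the highest. The pair-keeping splits of the treated comparisons number 8, too few for a share under 0.05. Silencing gave 813 genes against 0 as the highest other and 13 lists against 11. Overexpression gave 0 genes, as all 8 splits did, and 12 lists against 11.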

How the results depend on the processing

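Alternatives were planned except the exchange of 2 overexpression libraries, the 2 other sources alone, and the controls without ABD control source 4, which were chosen after the data were examined. Without the replicate block, silencing called 0 genes in place of 813 and HOTAIR had -1.86, no longer past the threshold, and the 78 other named genes lost their call. Differences between sources then enter the spread. The block across depots gave 606 genes in place of 803 between controls, whose same-numbered libraries had r between 0.056 and 0.49 and in 3 of 4 cases matched best. That is a hint of shared sources from the data, not the design. With this block 53 of the 74 other named genes kept their call. The TGF-beta and YAP list went from 2 to 0 lower, lipid storage from 3 to 1 higher, matrix from 4 to 2 higher, HOXD from 2 to 1 lower, patterning from 2 to 1 lower, the contractile list from 1 to 0 lower and inflammatory genes from 2 to 4 higher. The interferon list had 0 higher and 1 lower.

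With no filter on low counts silencing called 1566 genes, 805 of them among the 813. DESeq2 called 4 genes under overexpression, 2 in both manipulations and 2260 between controls. Exchanging 2 overexpression libraries gave 1 gene, STMN2, which was also called after silencing (1 in both). The 2 other sources alone gave 95, with 18 in both, HOTAIR among them. Of these 9 were higher with overexpression and lower after silencing (1.47 if independent), 6 the reverse (0.956) and 3 went the same way (2.40). The fit of 2 sources has 2 samples per group, so its calls rest largely on spread shared across genes. With no filter, 20 matrix genes fell after silencing, while 8 remodelling, 5 stromal, 4 histone and 4 mitochondrial ones rose. The contractile list then had 5 lower, and 4 with DESeq2, which also called 8 remodelling genes. Between controls DESeq2 called 10 immediate early, 7 lipid and 8 inflammatory genes higher and 5 TGF-beta and YAP genes lower. With no filter the controls had 0 TGF-beta and YAP genes lower, 4 HOXD genes lower and 1 stromal marker higher. The cause of the other shifts was not tested.

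Leaving out 1 source gave 294 to 540 genes for silencing, 7 to 2540 between controls and 3 to 15 lists for overexpression, against 12. Fewer samples alone would lower counts, but without source 4 the controls rose to 2540, and without ABD control source 4 to 2051.

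HOTAIR was past the threshold under overexpression with DESeq2 (4.42) and in the 2 other sources (3.39). Between controls it passed with the replicate block (3.66), in technical run 2 (3.68), with DESeq2 (3.58) and without ABD control source 4 (3.28), with 2.94 to 4.75 when 1 source was left out. With an estimated correlation, 0 lists were called in any of the 3 comparisons. Fry called 0 under overexpression, 8 after silencing, 5 of them among the 13 of camera, and 9 of the 12 between controls. Between controls fry did not call the TGF-beta and YAP, inflammatory and interferon lists (adjusted p = 0.165, 0.394 and 0.517).

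Of the named genes checked, none changed sign under any setting. STMN2 and HOX genes named without a call were left out of this check. Of 780 combinations of gene and setting for silencing, 550 kept the call and 230 lost it. Of 806 for the controls, 552 kept it and 254 lost it. RLE scaling changed no call among the named genes checked. Limma on TPM was not run, because those columns could not be matched to samples. Depth limits genes near 0 CPM most, above all in ABD control source 4 with 7932488 counts.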

Other observations

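STMN2 and the exchange of libraries it rests on were singled out only after the results were seen. The fit of controls without ABD control source 4 was also added then, and the other tests were planned. After silencing, steroid-related genes rose in 3 of 21 cases: HSD11B1, which regenerates cortisol (0.99 ± 0.09 on the log2 scale), the aromatase gene CYP19A1 (0.61 ± 0.06) and AKR1C1 (0.41 ± 0.07). Adjusted over the list alone, 4 rose and 2 fell. The list was not called (camera adjusted p = 0.0563), and its median was -0.02 although the test pointed up. Wnt pathway genes fell in 3 of 25 cases, TCF7L2 by -0.40 ± 0.07, SFRP2 by -0.54 ± 0.08 and WNT2 by -0.34 ± 0.08. Early adipogenic regulators fell in 2 of 21, EBF1 by -0.26 ± 0.05 and ZNF423 by -0.39 ± 0.10. Regional patterning genes fell in 3 of 24, among them MEIS2 (-0.31 ± 0.06) and IRX3 (-0.29 ± 0.06). Adjusted over the list alone, 5 Wnt, 6 adipogenic and 4 patterning genes fell, and 1 of each list rose. None of these 3 lists was called (adjusted p = 0.197, 0.123 and 0.0582). Without sources 1, 2, 3 and 4 the Wnt genes that fell were 2, 0, 2 and 3, the adipogenic ones 0, 1, 0 and 1 and the patterning ones 1, 0, 2 and 1.

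Genes of HOTAIR's protein partners split after silencing, JARID2 higher (0.31 ± 0.05) and EZH1 lower (-0.22 ± 0.05) of 17 measured (1 higher and 2 lower adjusted over the list alone). Among 23 lipid genes, with 2 higher and 2 lower adjusted over the list alone, G0S2, an inhibitor of lipolysis, rose by 0.61 ± 0.07, DGAT2 rose by 0.36 ± 0.08, and ACACA changed by -0.22 ± 0.05. In the hypoxia and glycolysis list 3 of 24 rose and ADM fell, as adjusted over the list alone, with HK2 at 0.48 ± 0.05 (camera adjusted p = 0.00327, adjusted p = 0.464 with an estimated correlation). Without sources 1, 2, 3 and 4 the hypoxia list had 1, 1, 1 and 2 higher, and the lipid list 1, 1, 1 and 2. EZH1 and ACACA passed in none of these 4 fits.

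STMN2, singled out after its values were seen, differed in opposite directions between the manipulations. It fell by 0.71 on the log2 scale after silencing (edgeR adjusted p = 0.0191, lower in 4 of 4 sources). With 2 overexpression libraries exchanged it rose by 1.26 (edgeR adjusted p = 0.00267, higher in 4 of 4 pairs), but as labelled it had 1.03 ± 1.65 with an adjusted p of 1.

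Between controls, interferon genes had a median of -1.53 with 32 of 34 negative, yet the 1 member past the threshold, IRF1, which also passed adjusted over the list alone, was higher in GF (1.14 ± 0.22; camera adjusted p = 0.00327, adjusted p = 0.839 with an estimated correlation). Inflammatory genes were higher in 2 of 26 cases, CXCL2 (3.52 ± 0.74) and NFKB1 (0.96 ± 0.23), with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00298, adjusted p = 0.751 with an estimated correlation). Neither list had a call without source 1, 2 or 3, and without source 4 the interferon list had 1 higher and 1 lower and the inflammatory list 6 and 3. With DESeq2, and without ABD control source 4 alone, 4 interferon genes were lower beside the 1 higher. The inflammatory list then had 8 higher and 1 lower, and 3 higher and 3 lower. SFRP2 was at 68.5 ± 28.9 CPM in GF and 3.47 ± 0.81 CPM in ABD controls (4.32 ± 0.38), and DKK3 at 63.3 ± 18.7 and 251 ± 85.4 CPM (-1.99 ± 0.30). CD68 was listed at 0 in each library, and whether its reads were lost in the counting was not tested.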
